A study of Triticum aestivum and Brassica napus with 9 samples.

How the data were processed

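Messenger RNA was sequenced from wheat root and rapeseed stem of seedlings grown on MS medium, per the labels' protocols. Total RNA was taken with a TRIzol kit and 3 µg went into each SMARTer mRNA library, per the labels' protocols. The aligner, the counting tool, the genome builds and the gene annotation are not given in the sources used here. Wheat and rapeseed each had a table of values per gene with exon coordinates, strand and length. The values are RPKM, reads scaled to the length of the gene model and to the reads of the library, as the authors deposited them per the names of the tables. The deposited RPKM values, multiplied by the model length, were whole multiples of 1 step per library for 100% of values (tolerance 0.001). The whole numbers summed to the library total that the scaling used, so the reads per gene behind the RPKM were rebuilt.

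Groups were taken from the labels: wheat treated on day 6 (3 samples, of which replicates 1 and 2 had a column), wheat control of day 2 (3) and rapeseed control of day 2 (3). Treated wheat replicate 3 was not analysed here. A further 3 columns of the rapeseed table matched no sample given and were not used here. The labels call the samples biological replicates without saying whether they came from separate cultures, so limma p-values measure the spread between these samples. Permutation p-values, taken over chromosomes, chromosome groups or shuffled calls, rest on the same libraries and do not measure that spread. Treatment and day differ together in wheat, and no comparison separates them. Rapeseed and wheat were never fitted together.

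The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(RPKM + 1), Benjamini-Hochberg adjustment and a threshold of 0.05, all chosen in advance. Genes needed 1 RPKM or more in at least 3 libraries, a filter written for 6 libraries and applied to the 5 held. Fold changes are on the log2(RPKM + 1) scale, which understates changes of low genes. An exact permutation test of 2 against 3 libraries cannot go below p = 0.1, so single genes rest on the limma model. The test was run on simulated wheat reads at the real depths with 200 genes changed, where 41649 genes were tested. It recovered 28% of genes raised 2-fold, 98.0% of those raised 4-fold, 27.1% of those lowered 2-fold and 81.6% of those lowered 4-fold. Of 41453 unchanged genes it called 16 higher and 92 lower. On the same simulated reads limma-voom recovered 70%, 100%, 41.7% and 83.7% in that order. It called 32 unchanged genes higher and 7 lower. Changes of 2-fold were thus recovered less often than changes of 4-fold in this simulation. Far more genes were called in the real data than the 200 changed here. The Benjamini-Hochberg cutoff depends on that share, so these rates and false calls do not carry over to the real test.

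The wheat table gives 21 sequences by accession and no chromosome names. They were assigned to chromosomes 1A to 7D in accession order, which the file does not state. Their lengths, taken as the last gene end, correlated with those of the chromosomes of the reference table (assembly IWGSC CS RefSeq v2.1) at 0.995, against at most 0.805 in 10000 random orders. Wheat and rapeseed coordinates are those of the deposited tables. No identifier of either table (0 matched) was found in the reference gene table, and the tables hold no descriptions. The 41 gene lists fixed before the data were examined therefore had 0 members and were not tested. The rule for named genes falls back on identifiers in that case: the 2 with the highest and the 2 with the lowest log2 fold change among called genes with a mean of 5 RPKM or more in the higher group and no overlap of libraries, and for rapeseed the 2 with the highest mean. The wheat table lists the exons of all transcripts of a gene, so that 15656 rows hold overlapping or touching entries. Exons were counted after merging such entries, which makes 369 wheat genes single-exon that are listed with more entries. Counting entries as listed, the single-exon differences given in the report were 8.11 points among higher and -2.98 points among lower genes. Rapeseed model lengths were all multiples of 3 and are called coding lengths. Reads shared between near-identical copies cannot be checked without sequences, and homeologous or duplicated genes are uncertain to that extent.

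Genes were grouped by subgenome, chromosome, position, exon number and length after the tables were seen. Differences in the share of called genes were taken per chromosome and tested with 100000 two-sided sign flips over 21 chromosomes, or all sign flips over 7 chromosome groups for subgenomes. The 21 chromosomes were flipped as separate units although homeologous ones carry related genes, so p-values over 21 chromosomes may be too small. Pairs of neighbouring tested genes both called the same way were compared with 1000 shuffles of the calls within each chromosome, one-sided. Adjusted p-values cover the tests of each family. A group counted as distal when it lay in the outer 10% of a sequence at either end. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

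Short models distort RPKM in the wheat table. The 1223 wheat models under 200 bases held 3.64 to 7.74% of the RPKM sum but 0.15 to 0.20% of reads. The highest RPKM of the treated libraries (25046 and 37524) came from a 12-base model with 794 and 3367 reads. Other settings, fixed before the data were examined, were other pseudocounts (0.1 and 0.5), other filters, median-ratio, quantile and TPM scaling, no trend, a robust fit, a replicate block, a 2-fold minimum and each library left out. Alternatives added after the tables were seen were a filter of 2 libraries, thinning of all wheat libraries to 2641775 reads in 10 draws, limma-voom on the rebuilt reads, models of 200 bases or more, and other distances for distal genes. The planned count tests were conditional on raw counts in the tables, which hold RPKM, and were not run.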

Results

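The series set hosts with and without symptoms against Sclerotinia sclerotiorum, a necrotrophic fungus that causes stem rot in many broad-leaved crops. Messenger RNA was sequenced from roots of wheat seedlings (Triticum aestivum, cultivar Zheng 9023) and from stems of rapeseed seedlings (Brassica napus, QingYou 1). Wheat was held as a group treated with the fungus, taken on day 6 (2 libraries), and a control group taken on day 2 (3 libraries). Rapeseed was held as a control group of day 2 (3 libraries). Treated wheat replicate 3 was not analysed here. The reads behind the deposited RPKM values numbered 2641775 and 7477466 in treated wheat replicates 1 and 2. They numbered 68478608, 72588593 and 71810489 in control wheat, and 71975934, 65675147 and 62949464 in control rapeseed. These totals count reads assigned to the listed genes of each host, and other reads were not analysed here. Treated wheat held far fewer assigned reads than its controls, and 1 read on a gene of 1 kb was worth 0.379 and 0.134 RPKM in the treated libraries against 0.0138 to 0.0146 RPKM in the controls. At least 1 read fell on 49838 and 59597 of the 82725 listed wheat genes in the treated libraries and on 75080 to 75539 in the controls. At 1 RPKM or more, the libraries were closer, with 38199 and 39191 genes in treated and 41266 to 41668 in control wheat.

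Root transcription in treated wheat of day 6 was far from that of control wheat of day 2. The question behind this comparison is how the root of a host responds to the fungus, but treatment and day changed together, so no difference can be given to one of them. Of 41095 genes tested, 8135 (19.8%) were higher and 15524 (37.8%) were lower in treated roots (limma on log2(RPKM + 1), Benjamini-Hochberg adjusted p under 0.05), and 17436 (42.4%) were not called. The median log2 fold change was 1.31 among the genes that rose and -1.34 among those that fell. Changes of 2-fold or more were found in 5398 higher and 10819 lower genes, and changes of 8-fold or more in 930 and 1269. The libraries of each group lay apart without overlap in all 23659 called genes and in 74.0% of tested genes, where chance gives 20%. Across genes, which are not independent replicates, the Pearson correlation of log2(RPKM + 1) was 0.934 between the treated libraries, 0.979 to 0.987 between controls and 0.725 to 0.764 between a treated and a control library.

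The split between higher and lower genes moved with quantile normalization, with limma-voom and with the filter on low values. The median log2 fold change over all tested genes was -0.31 with the values as deposited and -0.01 after quantile normalization. Quantile normalization called 10927 genes higher and 11577 lower, so that 48.6% of the calls were higher against 34.4% as deposited. That scaling gives every library the same distribution of values, which sets the median change near 0. Scaling by median ratios left 33.8% of the calls higher (8040 higher, 15730 lower) and scaling to TPM left 31.8% (7555 higher, 16167 lower). The limma-voom fit on the rebuilt reads called 7565 higher and 11973 lower (38.7% of calls higher). It kept 89.1% of the higher and 76.2% of the lower calls of the main test. The test also required 1 RPKM in 3 libraries, which a gene under 1 RPKM in every control cannot reach with 2 treated libraries. A requirement of 2 libraries, chosen after the tables were seen, gave 11501 higher and 16456 lower among 46662 genes (41.1% of calls higher). Genes under 1 RPKM in every control enter under that requirement only where both treated libraries reach 1 RPKM. Without control replicate 1, 2 or 3 the counts were 5359, 5623 and 5881 higher and 6199, 6311 and 7083 lower, where 3 of 4 remaining libraries also had to include a treated one. With 1 RPKM in 2 libraries the same fits gave 8823, 9101 and 9639 higher and 12080, 12303 and 13302 lower.

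**Figure D1:**
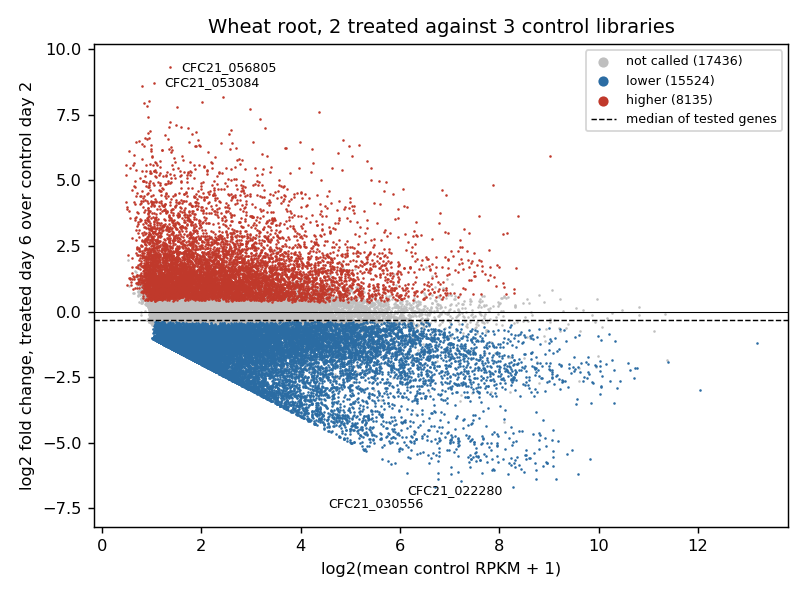
Log2 fold change of treated day 6 over control day 2 wheat root (vertical axis) against log2 of the mean control RPKM plus 1 (horizontal axis), 1 point per tested gene, for 2 treated and 3 control libraries. Red points are the 8135 genes higher, blue points the 15524 genes lower and grey points the 17436 genes not called, and the dashed line is the median of -0.31.

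Among the tested genes, which had 1 RPKM or more in at least 1 control, the genes named here had the highest and lowest log2 fold changes under the rule for named genes. Genes under 1 RPKM in every control were not ranked. CFC21_056805, a gene of 4 exons on chromosome 4B (94286327 to 94289115, plus strand), stood at 1605 ± 114 RPKM (SD, n = 2) in treated roots. Its control level was 1.58 ± 0.65 RPKM (SD, n = 3). The log2 fold change was 9.31 (SE 0.23, limma with Benjamini-Hochberg adjusted p = 0.000116). CFC21_053084, also of 4 exons, on chromosome 4A (564343784 to 564349245, minus strand), rose from 1.06 ± 0.84 RPKM (SD, n = 3) to 835 ± 160 RPKM (SD, n = 2). Its log2 fold change was 8.73 (SE 0.35, limma with Benjamini-Hochberg adjusted p = 0.000133). In the other direction, CFC21_022280, a gene of a single exon on chromosome 2B (161176328 to 161177215, minus strand), fell from 311 ± 49.8 RPKM (SD, n = 3) to 2.03 ± 0.74 RPKM (SD, n = 2). Its log2 fold change was -6.69 (SE 0.22, limma with Benjamini-Hochberg adjusted p = 0.00012), and both neighbouring tested genes also fell. CFC21_030556 on chromosome 2D (471962895 to 471962923, plus strand) had no read in either treated library. The controls held 187, 252 and 197 reads on it, or 103 ± 14.6 RPKM (SD, n = 3). Against a floor of 3 reads over the treated group this is at least 10.1-fold lower, a bound that covers counting error only. This model is 29 bases long, so its RPKM rests on few bases. The files pair none of these identifiers with a gene name or function.

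Genes under 1 RPKM in every library of 1 group (off) and at 5 RPKM or more in every library of the other (on) were counted against pools of unlike size. Off in this sense does not mean absent. Of 37893 genes under 1 RPKM in every control, 840 reached 5 RPKM or more in both treated libraries, and 25 of them had no read in any control. Conversely, of 17344 genes at 5 RPKM or more in every control, 950 stood under 1 RPKM in both treated libraries, 242 of them without a treated read. The counts of 25 and 242 cannot be compared, since the treated libraries held far fewer reads. Genes of a single exon were over-represented in the second set, relative to the genes that could enter it. Of the single-exon genes at 5 RPKM or more in every control, 12.6% fell under 1 RPKM in both treated libraries, against 4.63% of genes with more exons. The share was larger on 20 of 21 chromosomes (permutation test of sign flips, two-sided p = 1e-05, the smallest these can give, Benjamini-Hochberg adjusted p = 0.0001 over 10 such tests). Among models of 500 bases or more the shares were 12.4% and 4.67%. These shares, and those by position below, were neither matched on control level nor taken at equal depth. Whether control level or depth accounts for them was not tested. In the first set, 2.48% of single-exon genes under 1 RPKM in every control and 2.10% of those with more exons were switched on, a difference that did not pass (15 of 21 chromosomes, permutation test, adjusted p = 0.057). Both sets were more frequent towards chromosome ends. Genes switched on made up 2.49% of the genes under 1 RPKM in every control in the outer 20% at either end of a chromosome and 1.78% of those further in (19 of 21 chromosomes, permutation test, adjusted p = 0.00013). Genes switched off made up 6.22% and 4.76% of the genes at 5 RPKM or more in every control (14 of 21 chromosomes, permutation test, adjusted p = 0.0063). Both sets and all groupings by position, neighbours, exon number and length were chosen after the tables were seen. The wheat tests over chromosomes, here and below, use the same 5 libraries, so their p-values do not cover variation between libraries. Tests over 21 chromosomes also count homeologous chromosomes, which carry related genes, as separate units, so their p-values may be too small.

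Genes of a single exon were also over-represented among all genes that rose. Of 5679 such genes tested, 1521 (26.8%) were higher, against 18.7% of genes with more exons. The difference was 8.02 ± 2.79 percentage points (SD over 21 chromosomes) and was positive on all 21 (permutation test of sign flips, two-sided p = 1e-05, the smallest these can give, adjusted p = 3e-05). All 21 chromosomes were read from the same libraries, so this p-value does not cover variation between libraries. Homeologous chromosomes were counted as separate units, so it may also be too small. The difference stood at 7.27 points within 5 equal groups of control expression and at 7.27 points within 5 equal groups of gene length. Its size depended on the filter on low values, at 0.87 points without a filter (14 of 21 chromosomes, permutation p = 0.023), 12.05 with 1 RPKM in 2 libraries and 15.7 with a mean of 5 RPKM. With the last 2 filters, genes low in controls enter only through their treated values, so the rise itself decides part of the set. The main filter shares this limit in part, since genes at 1 RPKM in only 1 or 2 controls also need treated values to enter. Within 5 equal groups of control expression the differences were 1.84, 7.51 and 7.58 points in that order. Among genes that fell, single-exon genes were fewer, at 35.0% against 38.2% (-3.10 ± 3.25 points, p = 0.00049 by the same permutation test). This went against their larger share among genes switched off. That deficit among lower genes also depended on the filter, at -5.71 points with 1 RPKM in 2 libraries, -6.19 without a filter and -6.64 with a mean of 5 RPKM (all past the threshold). Without a filter, genes low in controls with little room to fall enter. Single-exon genes then made up 22.15% of the set, against 13.82% in the main test. In the main test the deficit was -0.99 points within 5 equal groups of control expression (permutation p = 0.16). It was -1.66 points (permutation p = 0.024) with all libraries thinned to equal depth and -0.74 points (permutation p = 0.28) without treated replicate 2. Shares of called genes among long genes went the other way. In the longest 20% of tested genes, of 2463 bases or more, 15.4% rose against 20.9% of the rest, on none of 21 chromosomes above. Of the same long genes 41.01% fell against 36.97%, on 20 of 21 chromosomes above (p = 1e-05 for both by the permutation test, adjusted p = 3e-05). These are shares of calls only. From the shortest to the longest 20% of tested genes, the median log2 fold change was -0.38, -0.26, -0.28, -0.31 and -0.34, without a steady fall with length.

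**Figure D2:**
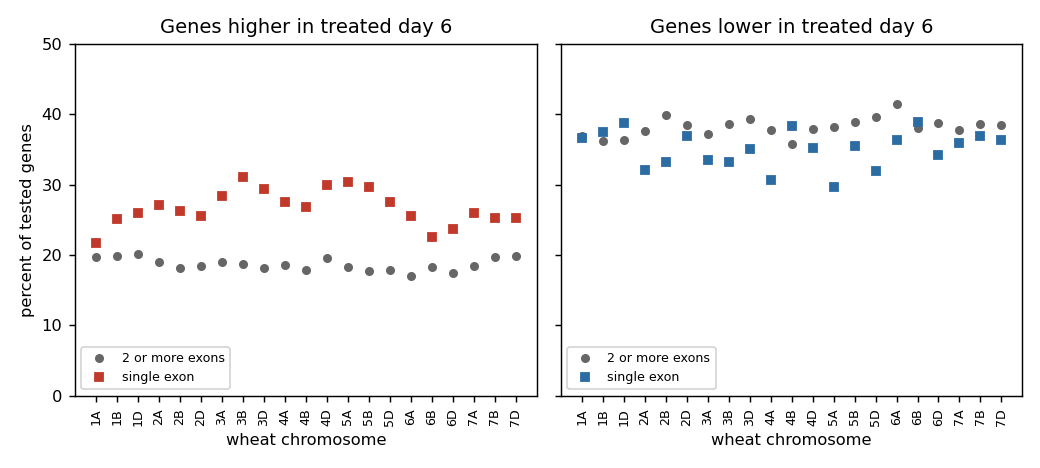
Percent of tested wheat genes higher (left) and lower (right) in treated day 6 roots, by chromosome, for genes of a single exon (squares) and of 2 or more exons (circles), each point a share of genes without error bar. On the left the squares lie above the circles on all 21 chromosomes (mean difference 8.02 points), and on the right they lie above on 4 of 21.

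Neighbouring genes changed together more often than shuffled calls did. Both members rose in 2081 of 41074 pairs of neighbouring tested genes, against 1608 on average when calls were shuffled within chromosomes, a ratio of 1.29. Both fell in 6488 pairs against 5861, a ratio of 1.11. The excess was larger among neighbours with the same number of exons and lengths within 10%, at 192 pairs against 50.1 for higher and 353 against 184 for lower genes, out of 1282 such pairs. Calls were shuffled over all tested genes of a chromosome, not within classes of exon number or length. A larger share of calls among the genes in such pairs may therefore enter this excess. Among the remaining, unlike neighbours the ratios were 1.21 and 1.08. With calls shuffled within windows of 50 tested genes and pairs at least 10 kb apart, they were 1.18 and 1.08. Each observed count was above all 1000 shuffles (one-sided permutation p = 0.001, the smallest these can give).

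Runs of consecutive tested genes showed the same. Runs of 6 or more higher genes numbered 17, against a mean of 1.86 and at most 9 in the shuffles, and runs of 10 or more lower genes numbered 10, against 1.504 and at most 8. On chromosome 4B, from 694118712 to 694641472, all 9 tested genes rose, with log2 fold changes from 0.53 to 5.37 and a median of 3.78. On chromosome 1A, from 359999860 to 361121516, all 9 tested genes rose as well (median 3.44), and on 1D, from 91915802 to 93212204, all 7 rose (median 2.72). The longest runs of lower genes held 13 genes on 1B (636601029 to 638998779, median -2.10, with 8 single-exon genes) and 13 on 2B (555709158 to 558012208, median -1.60). On 6B, from 34365339 to 36113607, 12 genes fell with a median of -4.28. No single run was longer than the longest in the shuffles (11 higher and 19 lower). Reads shared between near-identical copies were not checked in these runs.

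**Figure D3:**
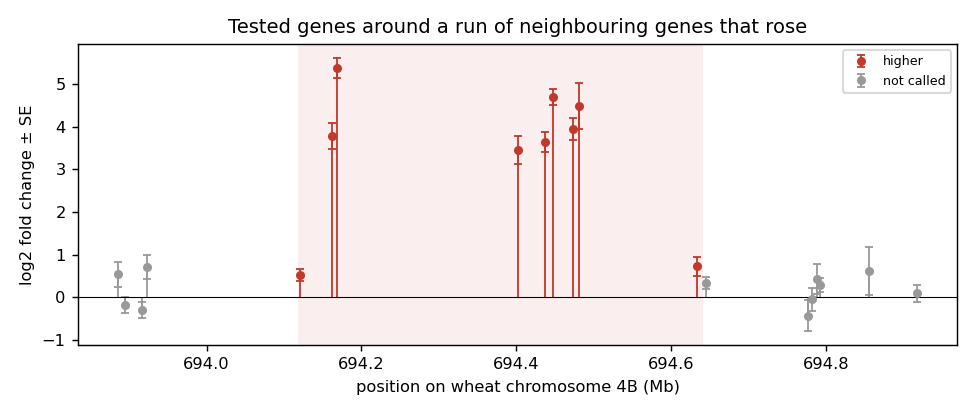
Log2 fold change with its SE (vertical axis) of each tested gene along part of wheat chromosome 4B in Mb (horizontal axis), treated day 6 over control day 2, red for genes higher and grey for genes not called. The shaded span from 694118712 to 694641472 holds 9 tested genes, all higher, with log2 fold changes from 0.53 to 5.37.

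The 3 subgenomes of wheat, the A, B and D sets of chromosomes that its ancestors brought together, did not differ past the threshold in their shares of changed genes. Shares of tested genes higher were 19.7% in A, 19.8% in B and 19.9% in D, and shares lower were 37.5%, 37.8% and 38.0%. None of the 6 differences passed an exact two-sided sign-flip test over the 7 chromosome groups (adjusted p = 0.80 for each). Single chromosomes ranged from 18.2% (6A) to 20.99% (1D) higher and from 36.1% (4B) to 40.7% (6A) lower. By position, 20.4% of genes in the outer 10% at either chromosome end rose against 19.6% further in, a difference of 0.68 ± 2.26 points (SD over 21 chromosomes) that did not pass (permutation p = 0.19). For the outer 20% the difference was 1.87 points (17 of 21 chromosomes, permutation test, adjusted p = 0.0011), and for the outer 5% it was -0.20 points (permutation p = 0.69). Without a filter the outer 10% gave -0.45 points (permutation p = 0.33). It passed at 1.06 points after quantile normalization (permutation p = 0.017) and at 2.40 points with a mean of 5 RPKM (permutation p = 0.024). With 1 RPKM required in 2 libraries it gave 3.04 ± 2.82 points (17 of 21 chromosomes, permutation p = 7e-05), but genes under 1 RPKM in every control enter that set only through their treated values, so the rise itself decides part of the set. Lower genes showed 37.7% and 37.8% (permutation p = 0.92). With 1 RPKM in 2 libraries these shares were 34.2% and 35.7%, a difference of -1.37 points (15 of 21 chromosomes below, permutation p = 0.0097). That difference was -0.51, -0.64 and -0.33 points with control 1, 2 or 3 also left out and -0.45 points after thinning, none of them past the threshold. Without a filter the difference among lower genes was -4.33 points (permutation p = 1e-05). That set also holds the genes under 1 RPKM in every control, which have little room to fall. Of 37893 such genes, 14427 lay in the outer 10%, against 11111 of the 41095 tested genes. The make-up of the set thus enters this difference, and by how much was not tested.

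Rapeseed stem was analysed as expression levels in a single group, without a comparison between groups. A mean of 1 RPKM or more was reached by 47159 of 77487 listed genes (60.9%), 100 RPKM by 1609 and 1000 RPKM by 54. Replicates were close, with a median coefficient of variation of 10.7% among expressed genes and 81.9% of them under 20%. The top gene was BnaC03g44340D, a single-exon gene with a coding length of 288 bases on C03 (29466062 to 29466349, minus strand), at 21826 ± 1679 RPKM (SD, n = 3). BnaA07g32420D, with 2 exons and a coding length of 588 bases on A07 (22475872 to 22476589, minus strand), followed at 7681 ± 715 RPKM (SD, n = 3). The A and C subgenomes, inherited from the turnip and cabbage lineages, held 46.6% and 53.03% of the listed genes and took 48.6 ± 0.22% and 51.2 ± 0.23% of reads (SD, n = 3). Expressed genes made up 63.1 ± 2.25% of those on the 10 A chromosomes and 60.3 ± 2.21% on the 9 C chromosomes (SD over chromosomes). This difference of 2.82 points passed an exact two-sided permutation test over chromosomes (p = 0.0137, adjusted p = 0.0275 over 2 measures). The chromosomes were taken as separate units, without pairing related A and C chromosomes, and were read from the same libraries. The p-value therefore does not cover variation between libraries. The median level of expressed genes did not differ past the threshold, at 6.16 RPKM for A and 6.09 RPKM for C (exact permutation p = 0.64).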

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

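Thinning, limma-voom, the filter of 2 libraries, the minimum model length and all results by position, exon number and neighbours were chosen after the data were seen. Over the alternatives, the higher and lower counts stayed within 1.5 times the main counts except for 5398 genes higher at a 2-fold minimum, 7707 genes lower at a mean of 5 RPKM (fewer genes tested), and fits without a replicate. Without 1 replicate the counts ran from 5359 to 8809 higher and from 6199 to 17643 lower, and a lone treated library was then assumed to vary like the controls. With the filter of 2 libraries, fits without a control gave 8823 to 9639 higher and 12080 to 13302 lower. The 4 wheat genes named kept direction and call in every alternative in which they were tested (19 to 23 each). The excess of single-exon genes among those higher kept its sign and passed under every alternative run, but its size moved with the filter. It was 0.87 points without a filter and 15.7 at a mean of 5 RPKM. The excess of neighbouring pairs over shuffled calls kept its sign and passed under every alternative run, from 0.18 to 0.55 for higher and from 0.065 to 0.22 for lower genes. The deficit of single-exon genes among those lower (-3.10) grew to -5.71 with the filter of 2 libraries, -6.19 without a filter and -6.64 at a mean of 5 RPKM. It was 3.78 points with the replicate block (permutation p = 3e-05), -1.01 with the filter of 2 libraries and control 2 left out, and between -4.13 and -0.74 without 1 replicate. The distal difference among genes higher (0.68, not past the threshold) was -0.45 without a filter and -0.20 for the outer 5%. It passed at 2.40 with a mean of 5 RPKM, 1.06 after quantile normalization, 1.87 for the outer 20%, 3.04 with the filter of 2 libraries, 2.72 with that filter after thinning, and 3.29, 3.07 and 2.95 with that filter and control 1, 2 or 3 left out. The distal difference among genes lower (-0.06) was 0.097 and 0.033 with pseudocounts of 0.1 and 0.5, 0.068 after quantile normalization, 0.045 without a trend, 0.84 with the replicate block (permutation p = 0.041), 0.35 with limma-voom and 0.53 thinned. It passed at -4.33 without a filter (permutation p = 1e-05) and at -1.37 with the filter of 2 libraries (permutation p = 0.0097), and was -0.45 with that filter after thinning and -0.51, -0.64 and -0.33 with that filter and control 1, 2 or 3 left out, all short of the threshold. The cause of these changes was not tested. Genes under 1 RPKM in every control enter without a filter and have little room to fall. They were more often distal and single-exon than the tested genes. Subgenome differences were compared by their largest size, since the signs of differences that did not pass varied between settings. The largest among genes lower had an adjusted p under the threshold only with a pseudocount of 0.1, where D lay above B by 0.48 points in 7 of 7 groups (exact p = 0.0156). The adjusted p was 0.047 over 3 pairs and 0.094 over all 6 tests. The replicate block, where only 2 numbers are shared and nothing says they pair samples, gave 6026 genes higher and 11867 lower. The settings fixed in advance for gene lists (camera, fry, homeologs merged) were not run, since the lists had no members, nor were the count tests.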

Other observations

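The tests of expression level and gene length for single-exon genes, under each filter, were chosen after the result was seen. Listed genes of the D subgenome were expressed more often than those of B in wheat roots. Of the listed wheat genes, 0 were without a read in every library used, so these are shares of detected genes. At 1 RPKM or more on the group mean, 51.7 ± 2.90% of listed D genes and 49.9 ± 2.92% of B genes were expressed in controls (SD over 7 chromosome groups). The difference of 1.79 ± 1.53 points was positive in 7 of 7 groups (exact sign-flip p = 0.0156, the smallest possible, adjusted p = 0.047 over 6 tests). In treated roots, over the same listed genes, the shares were 48.0% and 46.8%, a difference of 1.26 ± 0.84 points in 7 of 7 groups (exact p = 0.0156, adjusted p = 0.047). The A subgenome, at 50.7% in controls and 48.3% in treated roots, differed from neither past the threshold. At equal depth of 2641775 reads, the treated libraries spread their reads over fewer genes. They held 49838 and 54920 genes with a read, against 57889 to 58549 in controls, and their 100 strongest genes took 11.2% and 12.6% of reads against 10.3 to 10.9%.

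The first pattern is the count of genes changed. The tables argue against unequal depth as its whole cause: with all libraries thinned to equal depth, the lowest of 10 draws still gave 0.755 of the lower and 0.783 of the higher calls. Of the genes higher, 73.0% were also higher in 1 such draw, and 73.7% of those lower were also lower, with 0 in the opposite direction. Very short models made up 0.897% of the genes higher. The age of the seedlings and the fungus changed together, and which of them moved a gene stays open and untested.

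The second pattern is that neighbouring genes rose together. A regional trend broader than 50 tested genes would be removed by shuffling within windows of that size, and the ratio stayed at 1.24. A trend within a window is not removed by this shuffling, so narrower regional trends stay open. Reads shared between overlapping models would be removed by a gap of 10 kb, and the ratio was 1.22, or 1.18 with both. Neighbours unlike in exon number or length still gave 1.21, so like models alone do not account for it. For genes that fell together the ratios were smaller, at 1.096 within windows, 1.091 with the gap and 1.079 with both. Reads shared between near-identical distant copies stay open, since no sequences were at hand, and no biological explanation was tested.

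The third pattern is the rise of single-exon genes. Neither expression level (7.27 points within 5 equal groups of control expression) nor gene length (7.27 points within 5 equal groups of length) removed the difference of 8.02 points. The size moved with the filter: at a mean of 5 RPKM it was 15.7 points, or 7.58 matched on control and 15.1 on mean expression, and without a filter 0.87, or 1.84 and 4.58, so a part carried by expression level stays open. Genomic DNA in the treated libraries would lift models silent in controls, single-exon models among them. Over 4251 single-exon models under 0.05 RPKM in controls, the median treated level was 0 RPKM. That is a ratio of 0 to the median gain of 11.6 RPKM among single-exon genes higher. Of these models, 65.9% had no read in either treated library. The values argue against DNA as the source of gains of that size. A low level of DNA would leave many models without a read at the treated depth and stays open. No biological explanation was tested.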
